A study of Homo sapiens with 18 samples.

How the data were processed

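RNA was sequenced from primary human airway epithelial cells, RelA wild-type or RelA knockdown, at 0, 1 and 3 days of TGFb, in 18 libraries that the labels place in 6 groups of 3. Per the labels' protocols, total RNA was taken with an RNAqueous kit, and strand-specific libraries were made from 1 ug of it with Illumina's RiboZero Gold. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, STAR 2.5.1b, featureCounts 1.5.0-p1 and DESeq2 1.12.1, with the genome build GRCh38. The annotation release, the strand setting of the counting and any filters are not given in the sources used here. The deposited counts are whole numbers per Ensembl gene and library, not normalized, and totalled 5431773 to 13416950 per library. The totals ran from 6573693 to 7548838 (wild-type, day 0), 11565874 to 13416950 (day 1) and 8495386 to 10279450 (day 3), and from 9723161 to 13091551, 5431773 to 8261785 and 8344532 to 10689497 in knockdown cells. The authors also deposited DESeq2's regularized log (rlog) values on the log2 scale, in which 27 genes held text in place of a number and were left out. The rlog values served only an alternative test.

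Gene IDs were named from GENCODE release 29, which holds 49288 of the 50032 IDs. Transcript length (exon union) and GC content came from the same annotation. No counts were seen for 18511 genes. edgeR's filterByExpr with its defaults kept 14648, of which 12379 were protein-coding. IL6 had 17 counts in all and was not tested. Genes on the Y chromosome and the RNA genes of X inactivation were kept out of the listings. Other genes on the X chromosome stayed in.

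The counts were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests in a single fit of the 6 groups with TMM scaling and 12 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.00414, a biological coefficient of variation of 6.44%. An SE is the log2 fold change divided by the square root of F. The 10 comparisons were day 1 and day 3 against day 0 in each genotype, day 3 against day 1 in wild-type cells, knockdown against wild-type cells at each day, and the difference between genotypes in the day 1 and day 3 responses. The RELA level was also compared by an exact permutation test of log2 CPM.

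The 24 gene lists were tested with limma 3.58.1 (camera, preset correlation 0.01), adjusted over the lists of a comparison. They held epithelial, mesenchymal, EMT transcription factor, contractile, matrix, collagen processing, TGFb feedback, NF-kB target, NF-kB subunit, interferon-stimulated, cell-cycle, AP-1, protease, integrin, WNT, growth factor, unfolded protein response, glycolysis and p53 target genes, and markers of basal, secretory, ciliated, fibroblast, and blood and endothelial cells. The lists, the comparisons, the tests, the rule for named genes and a set of alternatives were fixed before the data were examined. The rule named RELA, CDH1, VIM, FN1, CDH2, SNAI1, SNAI2, ZEB1, COL1A1, MMP9, IL6, CXCL8 and NFKBIA whatever their values. It further named the protein-coding genes with the largest change each way among those past the threshold with a mean log2 CPM of at least 2 and with libraries that do not overlap between the 2 groups. These were 10 each way for day 3 against day 0 in wild-type cells, for knockdown against wild-type cells at days 0 and 3 and for the day 3 difference of responses, and 5 each way elsewhere. The demand on overlap was not made for the differences of responses. Up to 4 members of each list with the largest change past the threshold were added. Some genes that the rule took are not reported here.

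The alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate letter as a block, limma on the deposited rlog values, each library left out in turn, a fold threshold, and for lists an estimated correlation and limma's fry. Chosen after seeing the data were offsets that remove each library's loess trend on transcript length (span 0.3), the same with GC content, a fit without the 3 most abundant small RNA genes, and day 1 in place of day 0 as the reference. The length trend was measured over 11831 protein-coding genes as the median of the longest eighth (at least 10004 nt) minus that of the shortest eighth (at most 2434 nt).

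The tests were run first on simulated counts for 14648 genes with 200 changed genes. For wild-type day 3 against day 0, edgeR found 58.0%, 82.0%, 88.0% and 96.0% of genes changed 1.5, 2, 4 and 8-fold and called 7 unchanged genes. For the day 3 difference of responses it found 38.0%, 72.0%, 78.0% and 92.0% and called 11 unchanged genes. Far more genes passed in the real comparisons than were changed here, so these numbers do not give the error rates for that case. With a length trend added, edgeR called 5575 unchanged genes in the day 3 comparison of wild-type cells, 8131 between genotypes at day 0 and 7666 in the day 3 difference of responses. The length-adjusted fit called 25, 26 and 1. The added trend was measured in the real libraries by the same loess that this fit removes, so this part followed a look at the data. Its low numbers were built in and do not show how the fit handles another trend. Replicates of a group were compared before averaging, and no pair held identical values, with a chi-square per degree of freedom of 1.64 to 12.2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.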

Results

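RNA-seq counts were analysed from primary human airway epithelial cells that were RelA wild-type or carried a RelA knockdown, before TGFb (day 0) and after 1 and 3 days of TGFb. RELA encodes the p65 subunit of the transcription factor NF-kB. TGFb is a cytokine that drives epithelial cells through epithelial-mesenchymal transition (EMT), in which they lose epithelial traits and gain matrix and migration genes. The comparisons address the part RELA plays in the EMT of airway cells. The labels hold no group kept for 1 or 3 days without TGFb, so a TGFb effect cannot be told apart from time in culture. Each of the 6 groups had 3 libraries, lettered A, B and C, and the total counts of the 18 libraries ran from 5431773 to 13416950. Nothing in the labels says that the 3 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Of 50032 genes in the table, 14648 were tested. Changes are log2 fold changes ± standard error (SE) from edgeR, levels are CPM (counts scaled to library size) ± SD with n = 3, and p-values are adjusted by Benjamini-Hochberg from edgeR's quasi-likelihood test for genes and limma's camera for lists. A gene is said to have risen, fallen or differed where its adjusted p was below 0.05. The share of tested genes that passed ran from 54.6% (wild-type cells, day 3 against day 1) to 79.0% (between genotypes, day 0). Counts within lists are to be read against these shares.

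The share of long against short transcripts ran with the groups. Among 11831 protein-coding genes, the longest eighth lay 0.95 ± 0.047 log2 units against the shortest eighth in knockdown cells at day 0 and -0.93 ± 0.034 in wild-type cells at day 0 (mean ± SD, n = 3, each library relative to the mean of all libraries). The other groups lay at 0.47 ± 0.037 (wild-type, day 1), 0.27 ± 0.003 (wild-type, day 3), -0.61 ± 0.057 (knockdown, day 1) and -0.15 ± 0.12 (knockdown, day 3). The 3 most abundant small RNA genes, among them RMRP, the RNA of a processing ribonuclease, took 21.6% ± 0.767, 8.10% ± 0.284 and 13.5% ± 1.39 of counts in wild-type cells at days 0, 1 and 3, and 4.35% ± 0.674, 25.7% ± 0.784 and 18.7% ± 2.07 in knockdown cells. For each comparison the shift of long against short genes is given, and length-adjusted values, an alternative chosen after seeing the data, stand beside some of the gene groups.

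**Figure D1:**
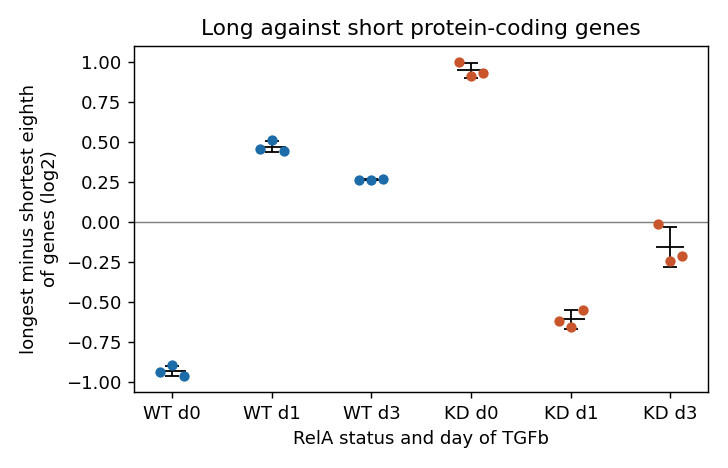
Longest eighth minus shortest eighth of protein-coding genes (log2, y axis) in each library, by RelA status (WT, wild-type, and KD, knockdown) and day of TGFb (x axis), with points for libraries and bars for the group mean and SD (n = 3). Knockdown day 0 sits highest at 0.95 and wild-type day 0 lowest at -0.93.

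RELA itself was lower in each knockdown library than in each wild-type library of the same day. The gene (ENSG00000173039.18, GRCh38 chromosome 11, 65653596 to 65663094, minus strand) stood at 84.0 ± 10.6, 50.6 ± 2.06 and 58.4 ± 6.90 CPM in wild-type cells at days 0, 1 and 3. Knockdown cells held 14.3 ± 1.16, 14.5 ± 0.109 and 7.93 ± 1.45 CPM, which is 17.0%, 28.6% and 13.6% of the wild-type level. The log2 differences were -2.55 ± 0.10, -1.80 ± 0.12 and -2.88 ± 0.13, with edgeR adjusted p-values of 3.46e-20, 5.32e-14 and 6.42e-19. An exact two-sided permutation test of log2 CPM gave p = 0.1 at each day, the smallest value that 3 libraries against 3 can give.

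**Figure D2:**
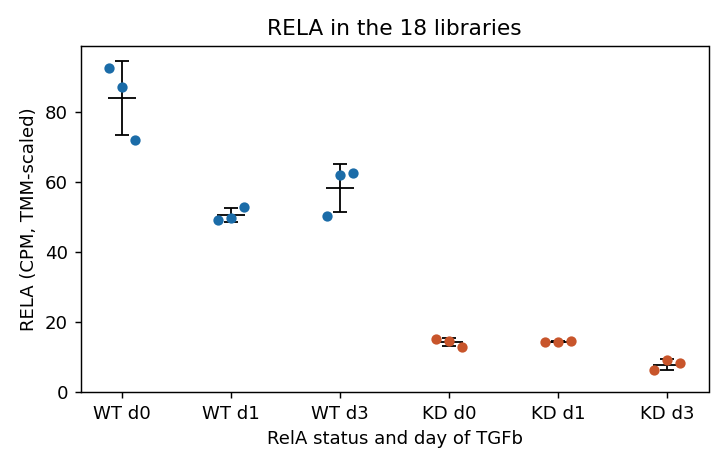
RELA level (CPM, y axis from 0) in each library by RelA status (WT, wild-type, and KD, knockdown) and day of TGFb (x axis), with points for libraries and bars for the group mean and SD (n = 3). The day 0 means are 84.0 and 14.3 CPM, and each knockdown library lies below the wild-type libraries of its day.

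In wild-type cells, matrix, mesenchymal and protease genes rose over 3 days of TGFb, and cell-cycle genes and part of the epithelial genes fell. FN1, which encodes the matrix protein fibronectin, went from 66.9 ± 6.07 to 25250 ± 768 CPM, a log2 change of 8.56 ± 0.07 (edgeR adjusted p = 4.53e-38). VIM, the intermediate filament of mesenchymal cells, rose by 6.42 ± 0.09, N-cadherin (CDH2) by 4.32 ± 0.23 and the fibrillar collagen COL1A1 by 5.12 ± 0.13. E-cadherin (CDH1), which joins epithelial cells, rose by 0.19 ± 0.06 (edgeR adjusted p = 0.00615), and its length-adjusted value was 0.12 (adjusted p = 0.0788). Over all genes tested, 5680 rose and 5206 fell, 3117 and 2368 of them by at least 1 log2 unit.

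Of the mesenchymal markers, 17 of 19 rose, with a median of 3.81 (camera adjusted p = 1.39e-46). Collagens and matrix proteins rose in 21 of 23 (camera adjusted p = 1.05e-48), among them the proteoglycan VCAN by 7.30 ± 0.15. Enzymes that modify collagen rose in 8 of 13 (camera adjusted p = 8.81e-04), and the cross-linking enzyme LOXL2 by 3.24 ± 0.36. Matrix proteases and their inhibitors rose in 19 of 20 (camera adjusted p = 3.39e-23), with the gelatinase MMP2 at 7.44 ± 0.18 and the metalloprotease ADAM19 at 7.24 ± 0.13, and MMP9 went from 0.377 ± 0.346 to 109 ± 5.07 CPM. EMT transcription factors rose in 10 of 12 (camera adjusted p = 1.73e-07), SNAI1 by 2.96 ± 0.44, SNAI2 by 2.93 ± 0.09 and HMGA2 by 4.60 ± 0.08. ZEB1 had no counts in the wild-type libraries at day 0 and was at least 4.51-fold higher at day 3, taken against a floor of 3 counts per library. Such floors cover counting error only. TGFb and SMAD feedback targets rose in 21 of 23 (camera adjusted p = 4.66e-17), PMEPA1 by 4.81 ± 0.09. Integrins rose in 12 of 13 (camera adjusted p = 5.20e-16), ITGB6, a subunit of an integrin that activates TGFb, by 5.62 ± 0.08. Contractile genes rose in 11 of 14 (camera adjusted p = 1.71e-06), the actin-binding TAGLN by 4.60 ± 0.13. WNT genes rose in 17 of 26 and growth factor ligands in 14 of 23 (camera adjusted p = 0.0272 and 0.0180), calls that were lost at adjusted p = 0.105 and 0.105 with an estimated correlation. Among the largest single rises were the transglutaminase TGM2 at 9.54 ± 0.17 and the proteoglycan SPOCK1 at 6.93 ± 0.17. Adjusted over the list alone, the counts of these 10 lists were the same.

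Each of the 24 measured cell-cycle genes fell, with a median of -2.49 (camera adjusted p = 9.80e-36), and all 24 fell adjusted over the list alone. The mitotic kinase PLK1 changed by -4.48 ± 0.11, CDC20 and UBE2C, which act with the anaphase-promoting complex, by -4.79 ± 0.09 and -4.14 ± 0.08, BIRC5 (survivin) by -3.55 and the kinesin KIF20A by -4.88. Epithelial junction and keratin genes fell in 20 of 28 and rose in 6, the counts being the same adjusted over the list alone (camera adjusted p = 1.04e-04). The simple keratin KRT19 stood at -5.32 ± 0.08, the tight-junction gene CLDN7 at -3.47 ± 0.07 and the epithelial transcription factor ELF3 at -3.68 ± 0.27. Among the largest falls were the aldehyde dehydrogenase ALDH3A1 at -8.31 ± 0.12, the basal-cell receptor NGFR at -6.79 ± 0.23, the basal keratin KRT15 at -5.50 ± 0.10 and the epithelial sodium channel subunits SCNN1B and SCNN1G at -6.58 and -5.33. Airway basal cell markers as a list went both ways, 8 up and 4 down of 13 (9 and 4 adjusted over the list alone), with a median of 0.78, a mean of -0.023 and an upward camera test that did not pass (adjusted p = 0.0934). Glycolysis and hexosamine genes fell in 14 of 23 and rose in 8, also adjusted over the list alone (camera adjusted p = 0.00927), with the glycolytic enzyme GPI at -2.10 ± 0.06. NF-kB target genes went both ways, 7 up and 15 down of 28 (7 and 16 adjusted over the list alone, camera adjusted p = 0.430). NFKBIA, the NF-kB inhibitor, changed by -0.62 ± 0.06, which turned to 0.12 with a length and GC adjustment. The chemokine CXCL8 changed by -0.76 ± 0.29 (edgeR adjusted p = 0.0193), a call lost without wild-type day 0 replicate C (-0.70) or day 3 replicate C (-0.57) and after the length adjustment (-0.33). Long genes moved by 1.20 log2 units against short genes here. The length-adjusted medians were 3.45 (mesenchymal), 2.53 (matrix), -2.50 (cell cycle) and -0.77 (epithelial), with adjusted p-values of 7.55e-13, 7.55e-13, 2.84e-16 and 9.73e-04.

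**Figure D3:**
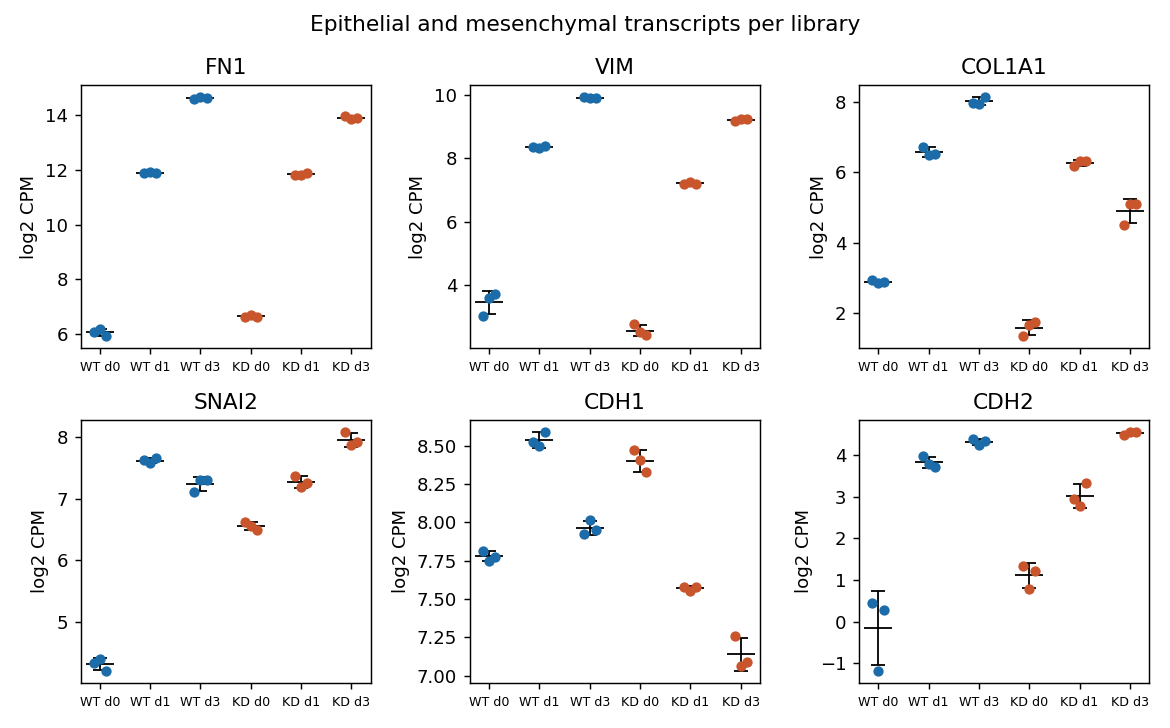
Level (log2 CPM, y axis) of EMT marker genes in each library by RelA status (WT, wild-type, and KD, knockdown) and day of TGFb (x axis), with points for libraries and bars for the group mean and SD (n = 3). FN1 rises by 8.56 in wild-type and 7.27 in knockdown cells from day 0 to day 3.

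After 1 day of TGFb, wild-type cells had already raised mesenchymal and matrix genes. FN1 rose by 5.84 ± 0.07, VIM by 4.87 ± 0.09, CDH2 by 3.84 ± 0.24 and COL1A1 by 3.69 ± 0.13. The EMT transcription factors SNAI1 and SNAI2 rose by 2.77 ± 0.44 and 3.31 ± 0.09, and CDH1 rose too, by 0.76 ± 0.06 (edgeR adjusted p = 4.08e-13, length-adjusted 0.61). TGM2 rose by 7.50 ± 0.19, the cytokine IL11 by 6.01 ± 0.29, ITGB6 by 5.36 and PMEPA1 by 4.66. Among the falls, ALDH3A1 stood at -4.80 ± 0.08, KRT15 at -4.18, the endocytic adaptor EPN3 at -3.99 and KRT19 at -3.73. Mesenchymal markers rose in 16 of 19, matrix genes in 21 of 23 and integrins in 11 of 13 (camera adjusted p = 9.16e-28, 1.23e-31 and 5.89e-15). Cell-cycle genes fell in 17 of 24 and rose in 5 (camera adjusted p = 0.00171). Unfolded protein response genes, which serve protein folding, rose in 13 of 20 and epithelial genes fell in 16 of 28 (camera adjusted p = 0.0160 and 0.0284), calls that were lost at adjusted p = 0.0887 and 0.0830 with an estimated correlation. Adjusted over the list alone, the counts of these 6 lists were the same. After the length adjustment the adjusted p-values were 1.10e-08 (mesenchymal), 9.50e-09 (matrix), 4.58e-05 (integrins), 0.0236 (cell cycle), 0.00472 (unfolded protein response) and 0.0264 (epithelial). The cell-cycle median went from -0.62 to -0.37 and that of the unfolded protein response from 0.35 to 0.59. Over all genes, 5989 rose and 5146 fell, and long genes moved by 1.5 against short genes.

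From day 1 to day 3, cell-cycle and protein-folding genes fell in wild-type cells, and matrix, protease and interferon-stimulated genes rose. FN1 rose by a further 2.72 ± 0.05, VIM by 1.55 ± 0.06 and MMP2 by 3.21 ± 0.10, whereas SNAI2 and CDH1 changed by -0.38 ± 0.07 and -0.57 ± 0.06. Cell-cycle genes fell in 23 of 24, also adjusted over the list alone (camera adjusted p = 1.25e-60), with the cyclin CCNB2 at -3.63 ± 0.12, the mitotic kinase NEK2 at -4.14 and DEPDC1 at -3.96. Unfolded protein response genes fell in 15 of 20 (16 adjusted over the list alone, camera adjusted p = 4.29e-09), among them the chaperones HSPA5 at -1.35 ± 0.06 and HSP90B1 at -1.42, and MANF at -2.17. Interferon-stimulated genes, an antiviral set, rose in 19 of 29, also adjusted over the list alone (camera adjusted p = 4.17e-05), with IFI44L at 2.27 ± 0.14, OAS1 at 2.17 and MX2 at 2.85. Matrix genes rose in 14 of 23 and proteases and their inhibitors in 11 of 20 (camera adjusted p = 9.57e-10 and 4.29e-09), and in 14 and 12 adjusted over the list alone. Fibroblast markers rose in 2 of 7, also adjusted over the list alone (camera adjusted p = 0.0411, but adjusted p = 0.0809 with an estimated correlation and 0.0558 after the length adjustment). The thioredoxin inhibitor TXNIP and the small heat shock protein CRYAB rose by 2.97 and 2.96. Of all genes, 3980 rose and 4023 fell, and long genes moved by -0.17 against short genes, the smallest shift of the 10 comparisons.

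Knockdown cells also raised matrix and mesenchymal genes under TGFb. By day 3, FN1 rose by 7.27 ± 0.07, VIM by 6.64 ± 0.09, COL1A1 by 3.33 ± 0.15, CDH2 by 3.37 ± 0.16 and SNAI2 by 1.40 ± 0.07, and CDH1 changed by -1.26 ± 0.06. TGM2, IL11 and the membrane glycoprotein PDPN rose by 9.35, 7.56 and 6.91. Mesenchymal markers rose in 16 of 19, matrix genes rose in 17 and fell in 4 of 23, and epithelial genes fell in 23 of 28 (camera adjusted p = 8.53e-31, 1.76e-18 and 1.34e-06). KRT15 and ELF3 stood at -4.50 and -4.71. Each of the 24 cell-cycle genes fell (camera adjusted p = 1.14e-14), the proliferation marker MKI67 at -4.17 ± 0.09 and PLK1 at -2.92 ± 0.12. Interferon-stimulated genes fell in 19 of 29 (camera adjusted p = 0.0191), OAS3 at -2.38 and IFIT3 at -1.59. Adjusted over the list alone, the counts of these 5 lists were the same. Glycolysis genes rose in 15 of 23 (16 adjusted over the list alone, camera adjusted p = 0.0181), with lactate dehydrogenase A (LDHA) at 2.04 ± 0.06. Length-adjusted p-values of the lists were 7.31e-11 (mesenchymal), 1.94e-08 (matrix), 5.41e-06 (epithelial), 8.33e-11 (cell cycle), 0.00694 (interferon-stimulated) and 0.00872 (glycolysis), adjusted over the lists. The desmosome-associated PPL, ALDH3A1 and SAPCD2 were among the largest falls, at -5.46, -5.71 and -5.44. KANK4, a regulator of the actin cytoskeleton, had no counts in knockdown cells at day 0 and was at least 401-fold higher at day 3, with the floor at 3 counts per library. Of all genes, 5125 rose and 5912 fell, and long genes moved by -1.09 against short genes. Knockdown day 3 replicate A stood apart from B and C, with a chi-square per degree of freedom of 12.2 and 9.63 against 1.64 between B and C.

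After 1 day of TGFb, FN1 rose by 5.19 ± 0.06 in knockdown cells, COL1A1 by 4.69 ± 0.14, VIM by 4.62 ± 0.09, SNAI1 by 2.82 ± 0.35, CDH2 by 1.91 ± 0.21 and SNAI2 by 0.71 ± 0.07, and CDH1 changed by -0.84 ± 0.06. TGM2 and IL11 were among the largest rises, at 9.50 and 7.94. Airway basal cell markers rose in 8 of 13 (camera adjusted p = 3.58e-06), among them KRT14 at 5.37 and KRT17 at 3.62, keratins with near-identical copies whose counts are uncertain. Glycolysis genes rose in 15 of 23 (camera adjusted p = 2.98e-05), GAPDH by 1.83 and TPI1 by 2.02. These counts were the same adjusted over the list alone, and the length adjustment gave adjusted p = 0.00685 (basal) and 9.06e-05 (glycolysis). PPARGC1A, a coactivator of mitochondrial biogenesis, and the transcription factor IKZF2 were among the largest falls, at -5.93 and -4.61. Of all genes, 5193 rose and 5924 fell. Long genes moved by -1.57 against short genes, against 1.5 in wild-type cells.

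Before TGFb, knockdown cells held more of the interferon-stimulated transcripts than wild-type cells. IFI6 differed by 4.36 ± 0.10, IFI27 by 4.48 ± 0.19, IFI44L by 4.82 ± 0.13, the RNA helicase DDX60 by 4.02 ± 0.11 and SAMD9L by 6.07 ± 0.31 (log2, knockdown minus wild-type). Interferon-stimulated genes were higher in 23 and lower in 3 of 29, also adjusted over the list alone, with a median of 2.63 (camera adjusted p = 1.61e-09) and a length-adjusted median of 2.5. Growth factor ligands were higher in 15 of 23, also adjusted over the list alone (camera adjusted p = 0.0187, but adjusted p = 0.309 with an estimated correlation). They included the EGF receptor ligands EREG at 4.15 ± 0.11 and AREG at 3.38 ± 0.08 and the cytokine TGFB2 at 2.55 ± 0.40. The other 22 lists did not pass the camera test at day 0. NF-kB target genes went both ways, 10 higher and 10 lower of 28, also adjusted over the list alone (camera adjusted p = 0.840). The inflammatory cytokines IL1A and CXCL8 were higher, at 3.06 ± 0.11 and 1.02 ± 0.22, as were SNAI2 at 2.25 ± 0.09, CDH2 at 1.16 ± 0.34 and CDH1 at 0.63 ± 0.06. VIM and COL1A1 were lower, at -0.91 ± 0.13 and -1.31 ± 0.21. The NF-kB subunit RELB stood at -1.62 ± 0.18, and at 0.058 with a length and GC adjustment. ZEB1 was at least 1.82-fold higher in knockdown cells, with the floor at 3 counts per library.

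Other large day 0 differences were the serine protease TMPRSS11E at 5.67 ± 0.21, PPARGC1A at 4.50 ± 0.12 and the mucosal keratin KRT4 at -5.83 ± 0.14. The replication histone genes HIST2H3D and HIST1H2AB stood at -4.89 ± 0.19 and -4.66 ± 0.13, and at -2.53 and -2.24 after the length adjustment. Both belong to families of near-identical copies, so their counts are uncertain. The glycolytic enzyme GAPDH stood at -1.88 ± 0.05 (length-adjusted -1.43). FN1 differed by 0.58 ± 0.06 but by -0.46 after the length adjustment, which turned its direction. Of all genes, 5958 were higher and 5608 lower in knockdown cells, and long genes stood 2.01 log2 units above short genes, the largest shift of the 8 comparisons of 2 groups.

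After 1 day of TGFb, interferon-stimulated and glycolysis genes were higher and collagen genes lower in knockdown than in wild-type cells. IFI27 differed by 7.05 ± 0.17, IFI6 by 6.42 ± 0.10, the antiviral GTPase MX1 by 4.26 ± 0.14 and the ubiquitin-like modifier ISG15 by 4.15 ± 0.23. Interferon-stimulated genes were higher in 28 of 29 (camera adjusted p = 1.17e-22, length-adjusted median 1.41). Glycolysis and hexosamine genes were higher in 15 of 23 (camera adjusted p = 8.25e-11), GPI at 2.09 ± 0.06, aldolase A (ALDOA) at 2.04 ± 0.07 and TPI1 at 1.84. Collagens and matrix proteins were lower in 18 of 23 (camera adjusted p = 2.06e-07, length-adjusted median -0.80), with COL5A2 at -2.60 ± 0.21, COL8A1 at -2.24 and COL12A1 at -1.92. NF-kB target genes were higher in 20 and lower in 5 of 28 (camera adjusted p = 0.0495, but adjusted p = 0.0964 with an estimated correlation), CXCL8 at 2.78 ± 0.20. Mesenchymal markers were lower in 11 of 19 and airway basal cell markers higher in 7 of 13 (camera adjusted p = 0.0495 and 0.0335), calls that were lost at adjusted p = 0.102 and 0.0964 with an estimated correlation. The length adjustment gave adjusted p = 0.120 (NF-kB targets), 0.241 (mesenchymal) and 0.120 (basal), and RLE scaling 0.0526 for NF-kB targets and 0.0621 for mesenchymal markers. Adjusted over the list alone, the counts of these 6 lists were the same. CDH1, CDH2 and VIM stood at -0.97 ± 0.06, -0.77 ± 0.16 and -1.15 ± 0.07. The troponin TNNI2, the peptide hormone UCN2 and the death ligand TNFSF10 were among the lowest, at -4.57, -3.88 and -3.25. Of all genes, 4611 were higher and 5448 lower, and long genes stood -1.12 against short genes.

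After 3 days of TGFb, knockdown cells held less of the collagen and matrix transcripts and more of the cell-cycle, interferon-stimulated and glycolysis transcripts than wild-type cells. COL1A1 stood at 30.2 ± 6.59 against 257 ± 20.5 CPM, a log2 difference of -3.10 ± 0.10 (edgeR adjusted p = 5.33e-22). COL7A1, the collagen of anchoring fibrils, differed by -3.64 ± 0.09, the basement membrane proteoglycan HSPG2 by -3.12 ± 0.10, the laminin chain LAMA5 by -3.87 ± 0.14 and COL16A1 by -2.64 ± 0.11. Collagens and matrix proteins were lower in 21 of 23, with a median of -1.18 (camera adjusted p = 1.76e-13) and a length-adjusted median of -1.03. Mesenchymal markers were lower in 14 of 19 (camera adjusted p = 0.00107), VIM at -0.69 ± 0.06, FN1 at -0.71 ± 0.05, S100A4 at -2.21 ± 0.62 and MMP2 at -1.71. Contractile genes were lower in 10 of 14 and TGFb and SMAD feedback targets in 16 of 23 (camera adjusted p = 0.0271 and 0.00984), calls that were lost at adjusted p = 0.148 and 0.176 with an estimated correlation. The contractile call was also lost after the length adjustment (adjusted p = 0.0937). Of the feedback targets, the SMAD repressors SKI and SMAD6 stood at -2.75 and -2.70. SNAI1 was lower at -1.91 ± 0.35, SNAI2 higher at 0.72 ± 0.07 and CDH1 lower at -0.82 ± 0.06. CDH2 stood at 22.2, 23.3 and 23.4 CPM in the knockdown libraries against 20.7, 18.8 and 20.3 CPM in the wild-type libraries. MMP9 stood at 5.72 ± 1.19 against 109 ± 5.07 CPM. IGFBP5, which binds insulin-like growth factors, had no counts in knockdown cells at day 3 and was at least 8.55-fold lower, with the floor at 3 counts per library.

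Cell-cycle genes were higher in 21 of 24 (camera adjusted p = 1.15e-06), the kinase CDK1 at 2.10 ± 0.10, the checkpoint kinase BUB1 at 1.97 ± 0.11, CDC20 at 1.89 and the cyclin CCNA2 at 1.64, and the cyclin CCNE2 was among the largest differences at 2.67 ± 0.23. Interferon-stimulated genes were higher in 24 and lower in 3 of 29 (camera adjusted p = 3.88e-07, length-adjusted median 1.30), IFI6 at 3.29 ± 0.09, IFI27 at 3.26 ± 0.15 and IFIT1 at 2.24. Glycolysis and hexosamine genes were higher in 16 of 23 (camera adjusted p = 0.00220), the glucose transporter SLC2A3 at 2.30 ± 0.43, hexokinase HK2 at 2.03 ± 0.11, LDHA at 1.36 and PGK1 at 1.32. Adjusted over the list alone, the counts of the matrix, mesenchymal, contractile, feedback, cell-cycle, interferon-stimulated and glycolysis lists were the same. NF-kB target genes went both ways, 9 higher and 14 lower of 28 (10 and 15 adjusted over the list alone, camera adjusted p = 0.681), with CXCL8 at 1.34 ± 0.25 and NFKBIA at 0.51 ± 0.06. TMPRSS11E, the peptide hormone ADM, the stress-response transcription factor DDIT3 and NGFR were higher, at 4.05, 3.12, 3.20 and 2.75, and the receptor NOTCH3 and the elastase inhibitor PI3 lower, at -4.21 ± 0.22 and -4.22 ± 0.12. Of all genes, 5147 were higher and 5244 lower, and long genes stood -0.45 against short genes. Upper-quartile scaling moved the median of all genes by -0.12 log2 units here and turned the direction of no gene named for this comparison.

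**Figure D4:**
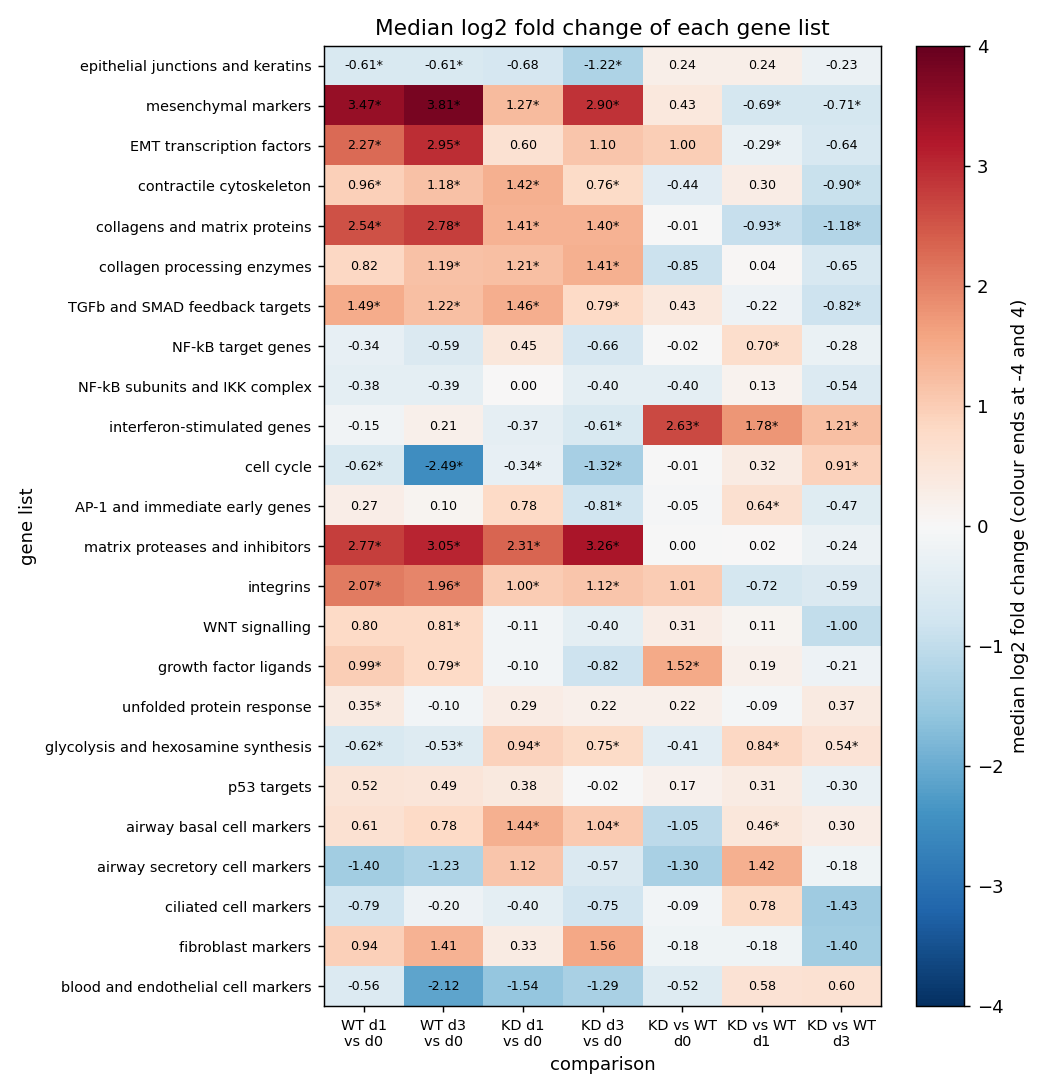
Median log2 fold change (colour and printed value) of the measured members of each gene list (y axis) in the comparisons of groups (x axis), with an asterisk where the camera adjusted p is below 0.05. Interferon-stimulated genes stand at 2.63 at day 0 and collagens and matrix proteins at -1.18 at day 3 in knockdown against wild-type cells.

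The change from day 0 to day 3 itself differed between genotypes, tested as the knockdown change minus the wild-type change. EMT transcription factors had a lower change in knockdown cells in 9 of 12 (camera adjusted p = 0.00636, but adjusted p = 0.0583 with an estimated correlation), SNAI1 by -2.50 ± 0.66, SNAI2 by -1.53 ± 0.11, SOX9 by -3.40 ± 0.26 and HMGA2 by -3.13 ± 0.11. Part of this came from day 0, where 9 of the 12 were higher and 0 lower in knockdown cells (median 1.00, camera adjusted p = 0.167). Between genotypes at day 3, 1 was higher and 7 lower (2 and 7 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0974). Matrix genes had a lower change in 18 of 23 (19 adjusted over the list alone, camera adjusted p = 1.93e-05, but adjusted p = 0.0583 with an estimated correlation). After the length adjustment the median of the matrix list went from -1.65 to -0.89 (adjusted p = 0.0695). VCAN differed by -3.16 ± 0.27, COL7A1 by -2.93 ± 0.12, the microfibril gene FBN1 by -2.66, HSPG2 by -2.58 and COL1A1 by -1.79 ± 0.24. FN1 differed by -1.29 ± 0.08, and by 0.0041 (adjusted p = 0.967) after the length adjustment. Interferon-stimulated genes had a lower change in 20 of 29 (21 adjusted over the list alone, camera adjusted p = 0.0380, but adjusted p = 0.0685 with an estimated correlation), IFI44L by -3.65, MX2 by -2.56 and the RNA sensor IFIH1 by -2.42. For MX2 the length-adjusted value of -1.51 did not pass (adjusted p = 0.0536). Mesenchymal markers, integrins and TGFb feedback targets had a lower change in 11 of 19, 11 of 13 and 14 of 23, and basal cell markers a higher one in 7 of 13. Their camera adjusted p-values of 0.0228, 0.0143, 0.0412 and 0.0380 rose to adjusted p = 0.0762, 0.0762, 0.275 and 0.0869 with an estimated correlation. The mesenchymal and integrin calls were also lost after the length adjustment (adjusted p = 0.0897 and 0.199).

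Cell-cycle genes had a higher change in knockdown cells in 19 of 24 (camera adjusted p = 2.05e-04, length-adjusted median 0.82), CDC20 by 3.69 ± 0.12, BIRC5 by 2.38 ± 0.14 and the cyclin CCNB1 by 2.16. Glycolysis genes had a higher change in 13 of 23 (camera adjusted p = 3.66e-05, length-adjusted median 1.07), TPI1 by 2.58 ± 0.08, GAPDH by 2.11 ± 0.07, PGK1 by 1.99 and ENO1 by 1.98. With length and GC adjusted, TPI1 and GAPDH differed by 1.53 and 1.23. The counts of the EMT factor, mesenchymal, integrin, feedback, basal, cell-cycle and glycolysis lists were the same adjusted over the list alone. CDH1 had a lower change by -1.45 ± 0.08 and TGFB2 by -3.16 ± 0.72. The cystine transporter SLC7A11, the transcriptional repressor PRDM1, VGLL3 and the kinase ROCK2 were among the most negative differences, at -4.99, -4.41, -4.27 and -3.98. The cytokine MIF was among the most positive, at 3.43. VIM did not pass at 0.22 ± 0.14, and limma on the deposited rlog values gave -0.27, past the threshold. Without wild-type day 0 replicate A, VIM passed at 0.39. CDH2 differed by -0.96 ± 0.36, a call lost without wild-type day 0 replicate B (-0.58) or knockdown day 0 replicate A (-0.83). The day 0 levels of CDH2 were low, at 0.442 to 1.36 CPM in wild-type and 1.72 to 2.54 CPM in knockdown libraries. At day 3 its level was not lower in knockdown cells. Of all genes, 4504 had a higher and 5660 a lower change in knockdown cells, and long genes moved by -2.43 against short genes. With day 1 in place of day 0 as the reference, chosen after seeing the data, several genes turned direction, VCAN to 0.74, SNAI2 to 1.07, TPI1 to -0.98 and GAPDH to -1.39.

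For the change from day 0 to day 1, glycolysis was the only list of the 24 that passed. Its genes had a higher change in knockdown cells in 14 and a lower one in 6 of 23 (14 and 7 adjusted over the list alone, camera adjusted p = 6.38e-05, length-adjusted median 1.08). TPI1 differed by 3.56 ± 0.08, GAPDH by 3.49 ± 0.07, ALDOA by 3.47 and GPI by 3.17. These 4 differences were 2.66, 2.74, 3.13 and 4.26 after the length adjustment and 1.36, 1.31, 2.17 and 3.47 with GC adjusted as well, all past the threshold. GAPDH stood highest where the 3 small RNA genes took most of the counts, at 7953 CPM with 21.6% (wild-type, day 0) and 7688 CPM with 25.7% (knockdown, day 1), and lowest at 2156 CPM with 4.35% (knockdown, day 0). SNAI2, CDH2 and CDH1 had a lower change in knockdown cells, at -2.60 ± 0.11, -1.93 ± 0.37 and -1.59 ± 0.08. CXCL8 differed by 1.76 ± 0.32, and its length-adjusted value of 0.64 did not pass (adjusted p = 0.0640). FN1 differed by -0.65 ± 0.08 and turned to 0.95 after the length adjustment. NKTR and TNNI2 were among the most negative differences, at -4.99 and -5.33. Of all genes, 5261 had a higher and 6242 a lower change in knockdown cells, and long genes moved by -3.16 against short genes, the largest shift of the 10 comparisons.

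The response of the other genotype was counted both ways. Choosing genes by their change in a genotype favours a smaller response in the other. Genes that moved the opposite way in the other genotype counted as responding less. Of 5485 genes that changed by at least 1 log2 unit from day 0 to day 3 in wild-type cells, 3733 responded less in knockdown cells by the test of the difference and 306 responded more. Of 5540 genes chosen the same way in knockdown cells, 3658 responded less in wild-type cells and 393 more. The shares that responded less were 68.1% and 66.0%. With day 1 in place of day 0 as the reference they were 56.1% of 1672 genes chosen in wild-type cells and 83.3% of 4059 chosen in knockdown cells.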

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

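The splits of the libraries and the test of library depth were set before the results were seen, and the tests of TGFb by itself and of preparation only after.

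The TGFb response differed between genotypes by the test of the difference in 11503 genes at day 1 and 10164 at day 3. At day 1 the named genes with a difference (knockdown minus wild-type response, log2) were CDH1 (-1.59), CDH2 (-1.93), SNAI2 (-2.60), FN1 (-0.65), CXCL8 (1.76), GAPDH (3.49), TPI1 (3.56), ALDOA (3.47), GPI (3.17), NKTR (-4.99), TNNI2 (-5.33), and the glycolysis list had a median of 1.10. At day 3 the EMT, adhesion and matrix genes with a difference were CDH1 (-1.45), CDH2 (-0.96), FN1 (-1.29), COL1A1 (-1.79), SNAI1 (-2.50), SNAI2 (-1.53), TGFB2 (-3.16), SOX9 (-3.40), HMGA2 (-3.13), VCAN (-3.16), COL7A1 (-2.93), HSPG2 (-2.58), FBN1 (-2.66). The cell-cycle and glycolysis genes with a difference were CDC20 (3.69), BIRC5 (2.38), CCNB1 (2.16), TPI1 (2.58), GAPDH (2.11), PGK1 (1.99), ENO1 (1.98). Others were IFI44L (-3.65), MX2 (-2.56), IFIH1 (-2.42), SLC7A11 (-4.99), PRDM1 (-4.41), VGLL3 (-4.27), ROCK2 (-3.98), MIF (3.43). The lists with a difference at day 3 had medians of -0.97 (mesenchymal), -1.58 (EMT transcription factors), -1.65 (matrix), -1.17 (TGFb feedback), -1.06 (interferon-stimulated), 1.31 (cell cycle), -0.97 (integrins), 0.99 (glycolysis) and 1.19 (basal cells). With an estimated correlation the cell-cycle and glycolysis lists passed, and the others did not, at adjusted p = 0.0762 (mesenchymal), 0.0583 (EMT transcription factors), 0.0583 (matrix), 0.275 (TGFb feedback), 0.0685 (interferon-stimulated), 0.0762 (integrins) and 0.0869 (basal cells).

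In splits that exchanged genotype labels within day 0 and within the later day, 50 were drawn and 1 gave as many genes as the real one at day 1, the real one itself, and the highest other gave 8757. At day 3 it was 1 of 50, with 8246 in the highest other. These splits mix genotypes that differ at each day within a group, which favours the real labels, so they do not test whether the TGFb responses were equal. For each comparison of 2 groups, 1 of 10 splits gave as many genes as the real one, and the highest other gave 0 genes. The real counts were 11135, 10886 and 8003 in wild-type cells (day 1, day 3, and day 3 against day 1), 11117 and 11037 in knockdown cells, and 11566, 10059 and 10391 between genotypes at days 0, 1 and 3. With 10 splits no share under 0.05 can be had.

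Long genes moved against short genes between groups, and both differences of responses carry the trend, at -3.16 and -2.43 log2 units. Library depth is argued against as the whole cause, since with every library thinned to 5431773 counts the day 0 gap between genotypes was 1.85, against 1.88 with all counts. TGFb by itself is argued against by the day 1 shift, -1.57 in knockdown and 1.5 in wild-type cells. RNA or library preparation may be the source and cannot be told apart from the groups, because the labels give no preparation batch and replicates of a group shared the trend, with a largest SD within a group of 0.12. A difference in long transcripts that belongs to RelA status and TGFb together stays open as well, untested.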

How the results depend on the processing

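The length adjustments, the fit without the 3 small RNA genes and day 1 as the reference were chosen only after the results were seen. Over all alternatives, values of named genes kept direction and side of the threshold in 4121 cases, were no longer past it in 21, came past it in 3 and turned in 46. Counts stayed within 1.5 times in 215 cases and moved further in 16, and RELA stayed lower and past the threshold in all 51. Tests of lists were kept in 385 cases and lost in 40, 23 of them with an estimated correlation, 10 with the length adjustment, 4 with the replicate block and 3 with RLE scaling. The cause was not tested for any of these or the changes that follow, unless given.

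With a fold of at least 1 log2 unit also required, the counts in wild-type cells were 5723 (day 1), 5485 (day 3) and 1672 (day 3 against day 1), in knockdown cells 6323 and 5540, between genotypes 7190, 4115 and 4570 at days 0, 1 and 3, and 6598 for the day 3 difference of responses. fry called 214 of 240 list tests against 85 by camera. Of genes chosen in wild-type cells, those with a smaller or opposite response in knockdown cells numbered 1564 of 2156 with limma on rlog values. They numbered 6871 of 10886 with no fold required. With day 1 as the reference they numbered 938 of 1672 and 934 of 1668, without and with the length adjustment. For genes chosen in knockdown cells, the numbers with a smaller or opposite response in wild-type cells follow in the same order. They were 1376 of 2020, 6864 of 11037, 3380 of 4059 and 3357 of 4046.

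With day 1 in place of day 0, directions turned for wild-type cells at day 3 in SNAI2 -0.38, CDH1 -0.57, GPI 0.018 (length-adjusted SNAI2 -0.38, CDH1 -0.49, GPI 0.093). In knockdown cells they turned in COL1A1 -1.36, TGM2 -0.15, IL11 -0.39, IFIT3 0.71 (length-adjusted COL1A1 -1.50, TGM2 -0.24, IL11 -0.24, IFIT3 0.86). In the day 3 difference of responses they turned in CDH1 0.15, CDH2 0.97, SNAI2 1.07, VCAN 0.74, FBN1 0.49, TPI1 -0.98, GAPDH -1.39, ENO1 -1.04, VGLL3 0.41, ROCK2 0.57, MIF -1.35 (length-adjusted CDH1 0.095, CDH2 0.95, SNAI2 1.19, VCAN 0.47, FBN1 0.20, TPI1 -0.79, GAPDH -1.23, ENO1 -1.06, VGLL3 0.16, ROCK2 0.34, MIF -1.0). This alternative compares other times, so part of the change is its own construction. The length adjustment turned FN1 -0.46 between genotypes at day 0 and FN1 0.95 and FN1 0.0041 in the day 1 and day 3 differences of responses. With GC as well, FN1 stood at -1.17, 2.0 and 0.26, NFKBIA 0.12 at day 3 in wild-type cells and RELB 0.058 and 0.027 between genotypes at days 0 and 3. Limma on rlog values turned VIM -0.27 in the day 3 difference of responses.

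Leaving out 1 library at a time gave 10719 to 10954, 10477 to 10688 and 7291 to 7465 genes in wild-type cells, 10666 to 10902 and 10483 to 10762 in knockdown cells, 11242 to 11414, 9441 to 9809 and 9912 to 10156 between genotypes, and 11377 to 11580 and 9890 to 10092 for the differences of responses. The RELA difference ranged over -2.64 to -2.47, -1.84 to -1.78 and -3.00 to -2.72. The letters A, B and C showed no clear pairing of the libraries. Deviations of same-letter libraries correlated with a mean of 0.016 (-0.27 to 0.58), and above 0.1 in 9 of 45 pairs. Those of other letters correlated with a mean of -0.0078 (-0.53 to 0.43). Pairing between some of the groups is not excluded by these values. With the letter as a replicate block, the genes changed by TGFb at day 3 in RelA wild-type cells numbered 10842 and the genes changed by RelA knockdown at day 3 of TGFb 10358, no named gene changed its call and 81 list tests passed. The calls lost were those of mesenchymal markers, EMT transcription factors, NF-kB target genes and AP-1 and immediate early genes between genotypes at day 1 (adjusted p = 0.0812, 0.0575, 0.0571 and 0.0571). The shallowest library held 5431773 counts, which limits what can be seen of genes near the filter.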

Other observations

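The tests of gene length, of fibroblasts, of the knockdown procedure and of blood markers without CD68 were chosen only after the result was seen.

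At day 3, NF-kB subunits and IKK genes were lower in knockdown than in wild-type cells in 9 and higher in 3 of 15 (camera adjusted p = 0.192). RELA is itself a member, and NFKB2 stood at -1.44 ± 0.12, RELB at -1.12 ± 0.18 (turned to 0.027 with length and GC adjusted) and MAP3K14, the NF-kB inducing kinase, at -1.62 ± 0.27. AP-1 and immediate early genes were lower in 8 and higher in 4 of 14 (camera adjusted p = 0.347), with JUND at -2.07 ± 0.14, FOS at -1.98 ± 0.16 and ATF3 at 1.47 ± 0.14. The AP-1 list passed between days 1 and 3 in wild-type cells, from day 0 to day 3 in knockdown cells and between genotypes at day 1 (camera adjusted p = 0.0381, 0.0181 and 0.0495), but not at adjusted p = 0.282, 0.175 and 0.299 with an estimated correlation. EMT transcription factors passed between genotypes at day 1 (camera adjusted p = 0.0495), but not at adjusted p = 0.160 with an estimated correlation. Growth factor ligands at day 1 in wild-type cells likewise passed by camera with the preset correlation (adjusted p = 0.00521). They did not pass by camera with an estimated correlation (adjusted p = 0.0830). The p53 targets were higher in 5 and lower in 9 of 17 between genotypes at day 3 (5 and 10 adjusted over the list alone, camera adjusted p = 0.433), with the stress-response gene SESN2 at -2.29 ± 0.09. Of 16 secretory cell markers 4 were measured and 1 was lower, and of 13 ciliated cell markers 3 were measured and 2 were lower (camera adjusted p = 0.862 and 0.538). Blood and endothelial markers were higher in 1 of 3 measured (camera adjusted p = 0.463). Except for the p53 targets, these day 3 counts were the same adjusted over the list alone.

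Interferon-stimulated genes were higher in knockdown cells at each day. The gene length trend is argued against as the whole cause, since the length-adjusted median stayed at 1.30 or above. The list was not tested with GC content adjusted as well. Blood or immune cells stay open, because the bound of 10 CPM on their summed markers, set before the result was seen, was wrong: CD68 alone stood at 31.4 to 44.7 CPM in the wild-type groups and made 99.7 of the 101 CPM in knockdown cells at day 3. Without CD68 the sums were 4.25 ± 1.18, 1.46 ± 1.04 and 1.75 ± 0.968 CPM in knockdown cells at days 0, 1 and 3 against 11.8 ± 1.96, 1.39 ± 0.312 and 0.787 ± 0.183 in wild-type cells (mean ± SD, n = 3), lower at day 0 (CD14 made 9.51 CPM of the wild-type sum) and within the spread at days 1 and 3 (largest difference 0.964 CPM, at day 3), with the leukocyte gene PTPRC at most 0.145 CPM in a knockdown group, which does not settle it because the ratio of these markers to interferon-stimulated transcripts in such cells is not known here. The knockdown procedure may raise these genes apart from the loss of RELA (median 2.63 at day 0), and this cannot be told apart because the labels give no group with a control construct.

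Matrix genes were lower in knockdown cells at day 3. The gene length trend is argued against as the whole cause by the length-adjusted median of -1.03. This list was not tested with GC content adjusted as well. Fewer fibroblasts are argued against as the source of the COL1A1 difference of 227 CPM, since such cells would bring their other abundant transcripts along. The other matrix genes were not covered by this test. A first test, on the median of the fibroblast markers, was undecided and was replaced by this one after the values were seen. In wild-type cells at day 3, COL1A2 stood at 0.278, COL3A1 at 0.0366, LUM at 0.0366 and DCN at 0.950 CPM, and COL1A2, COL3A1 and LUM had 10, 3 and 12 counts over the 18 libraries. The fibroblast markers had a median of -1.40 over 7 measured of 13, 4 lower and 2 higher (camera adjusted p = 0.280), with PDGFRB, FBLN2 and FBLN1 at -2.79, -2.35 and -1.57 but DCN at 2.40 ± 0.40, and the loss of RELA itself and the knockdown procedure stay open, untested.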
